A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

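Poly(A) RNA was sequenced with strand-specific libraries (dUTP method) from 8 budding yeast cultures. There were 2 libraries each of wild-type BY4741 untreated, after 10 min and after 60 min of 200 ng/mL rapamycin at 30 °C, and 1 library each of prp4-1 and prp4-1 pGAL-IFH1 at 26 °C. Per the submitters' processing notes, reads were mapped to sacCer3 with TopHat and Bowtie, whose versions are not given there.

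The deposited gene table held scaled signal for 6569 genes, with the authors' group averages, which were means of the scaled columns to within 5e-06. How the authors chose the scaling of a library is not stated. Median-of-ratios factors computed from the scaled signal, separately in the 6 wild-type and the 2 prp4-1 libraries, lay within 0.417% of 1, and levels in the 2 sets are not set on a common scale here. Another 8 columns of unscaled signal were not used, because their names give a group but no replicate and each group already had its libraries' scaled columns. How reads were summarised per gene, and whether over exons or whole spans, is not stated, so the number of reads behind a value is unknown and no counting interval is given. Total scaled signal ran from 2025663 to 3319861 per library.

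Each gene's place was deposited with its signal. The deposited gene models (other: exon coordinates, counted from 1) gave strand and introns for the 6439 genes found there by name. For the rest, models under a variant of the name or the R64 reference annotation were used. HAC1 was counted as without an intron. Of 5942 names matched to the R64 reference annotation, 97.0% had the same coordinates. Introns were found in 280 genes, 97 of them for cytosolic ribosomal proteins, against 255 genes by R64.

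Columns were assigned to groups by their names. They carry library numbers but no replicate number, so libraries were not paired. Comparisons in wild type used limma 3.58.1 in R 4.3.3, with an intensity trend in the variance, on log2 of scaled signal plus a pseudocount of 1, for the 6127 genes with a mean of at least 1. The 6 libraries were fitted together, with group as the only term. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and means and SDs are of scaled signal. Where leaving out a library left a group with 1, that library was assumed to vary like the other groups.

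The lists of genes were fixed before the data were examined. They were cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, RNA polymerase I and III subunits, nitrogen catabolite repression, general stress response, Hsf1 chaperones, retrograde response, autophagy, proteasome, Gcn4 amino acid biosynthesis, adenine biosynthesis, respiratory chain and ATP synthase, spliceosome and splicing factors, mRNA decay, G1 cyclins and histones, meiotic genes with introns, the GAL regulon, autoregulated genes with introns, and the a-specific, alpha-specific and auxotrophic marker genes used to check labels. Intron-containing genes outside the ribosomal protein list, and ribosomal protein genes with and without introns, were tested as well. HIS3 and RPA14 were not analysed here. ATG31, tested as a gene under its other name CIS1, was left out of the autophagy list because the names were not matched. Each list was compared with all other tested genes by limma's camera, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists and both times, or over the lists for 60 against 10 min. The fry test, which does not compare a list with other genes, was run as well.

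Genes named were the 10 largest rises and 10 largest falls at each time among called genes with a mean signal of at least 10 whose treated libraries both lay beyond both untreated libraries, and the 2 members of each list with the smallest p. For 60 against 10 min the 5 largest rises and falls are named. The overlap of the calls was set against 50 simulations of unchanged groups, in which the untreated libraries were also simulated and shared by both times.

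For the prp4-1 pair no test was made. Log2 ratios of signal plus 1 were computed for 6222 genes with a mean of at least 1, and each list's median was placed among 10000 random lists matched in 20 bins of mean signal, the percentile being its place among them. Genes with the 10 highest and 10 lowest ratios and a mean signal of at least 10 in the pair are named.

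The methods were tested on simulated data. With 200 changed genes among 6127, limma recovered 92.5% of 1.5-fold, 98.5% of 2-fold and 95.5% of 4-fold changes at 10 min, with 26 calls among unchanged genes, and 88.1%, 91.0% and 100% at 60 min, with 13. The camera test called a shifted list, and 2 of 100 random lists had an unadjusted p under 0.05. Among 100 lists of 50 genes in the prp4-1 pair, 3 without a shift lay under the 2.5 percentile and 4 over the 97.5 percentile. Under the 2.5 percentile were 74 lowered by 0.5 and 100 lowered by 1 on the log2 scale. Genes varied independently of each other in all these simulations. Error rates for lists whose genes vary together were thus not checked.

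The alternatives were median-of-ratios scaling over all genes and without ribosomal protein and ribosome biogenesis genes, no filter, a pseudocount of 0.1 (0.5 and 5 for the pair), a 2-fold minimum, only the 4 libraries compared, each library left out in turn, and an estimated correlation or fry for the lists. Total-signal scaling in wild type, the set of library numbers as a term, median-of-ratios scaling of the pair, weighting by exon length, each time against a different untreated library for the overlap, and all alternatives for the genes with opposite calls were chosen after seeing the data. Splicing of introns was planned but could not be computed, since the files analysed give no values for introns, junctions or unspliced transcripts. Tests that need counts of reads were not possible for the same kind of reason, since no counts per gene are given.

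Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and figures.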

Results

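Poly(A) RNA of budding yeast was sequenced from strand-specific libraries to follow transcript levels when ribosomal protein gene transcription was turned down. The laboratory strain BY4741, a MATa wild type, was grown at 30 °C in rich medium to an optical density of 0.5. It was left untreated or given 200 ng/mL rapamycin, an inhibitor of the TORC1 growth-control kinase, for 10 or 60 min. Each of these groups had 2 biological replicates. The other comparison set a prp4-1 strain, which carries a mutation in a spliceosomal protein, against a prp4-1 strain with IFH1 under the GAL1 promoter, labelled as having IFH1 lowered by about 50%. Both were grown at 26 °C, with 1 library each. The values were signal per gene for 6569 genes on the sacCer3 build. Summed scaled signal ran from 2025663 to 3319861 per library, and the number of reads behind it is unknown. Replicates correlated across genes at r = 0.994 for the untreated, 0.996 for the 10 min and 0.996 for the 60 min libraries, and genes are not independent replicates.

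The comparison of 10 min with untreated cells asked what changed first after the drug. Genes of nitrogen catabolite repression, which serve the use of poor nitrogen sources, showed the steepest rises. GAP1, the general amino acid permease (chromosome XI, 515063 to 516871), rose from 25.6 ± 5.41 to 2762 ± 173 (scaled signal, mean ± SD, n = 2), a log2 change of 6.71 (SE 0.130, limma adjusted p = 5.08e-08). The ammonium transporter MEP2 (chromosome XIV, 357453 to 358952) rose from 29.7 ± 1.99 to 2296 ± 152, a log2 change of 6.22 (SE 0.0792, limma adjusted p = 9.98e-09). The other genes among the 10 largest rises were the urea amidolyase gene DUR1,2 (log2 change 5.21), the GATA factor gene DAL80 (5.07), the urea transporter gene DUR3 (4.95), the proline permease gene PUT4 (4.85), the amino acid permease gene AGP1 (4.78), DAL3 of allantoin breakdown (4.62), the oligopeptide transporter gene OPT2 (4.53) and the ammonium transporter gene MEP1 (4.29). Of the 28 nitrogen catabolite repression genes, 27 rose and 0 fell, with the same counts adjusted over the list alone. The list's median log2 change was 2.74 (camera adjusted p = 1.33e-18; adjusted p = 0.0568 with an estimated correlation).

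Genes of ribosome assembly were among the largest falls at 10 min, together with TOD6. TOD6, a repressor that binds ribosome biogenesis promoters (chromosome II, 117589 to 119166), fell from 218.6 ± 20.4 to 5.92 ± 0.168 (scaled signal, mean ± SD, n = 2), a log2 change of -4.99 (SE 0.125, limma adjusted p = 9.94e-08). NOG2, a GTPase gene of large-subunit assembly that holds an intron (chromosome XIV, 721120 to 723112), fell from 406.7 ± 15.6 to 15.4 ± 0.757. The remaining 8 of the 10 largest falls were DHR2 (log2 change -4.57), ATC1 (-4.32), SSF1 (-4.26), GFD2 (-4.13), RRP36 (-4.09), NOG1 (-4.03), RSA4 (-3.98) and RFU1 (-3.92). All 121 genes of the ribosome biogenesis list fell, with the same count adjusted over the list alone. BFR2 was another with a small p, at a log2 change of -3.83. The median of the list was -2.52 (camera adjusted p = 1.11e-43; adjusted p = 0.174 with an estimated correlation). All 19 measured RNA polymerase I and III subunit genes fell, 19 adjusted over the list alone, with a median of -1.63 (camera adjusted p = 1.12e-10; adjusted p = 0.124 with an estimated correlation). Examples were RPA135 at -2.25 and RPA43 at -2.21.

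The cytosolic ribosomal protein genes moved far less at 10 min. Of 137, 116 fell and 1 rose, and 121 fell and 1 rose adjusted over the list alone. Their median log2 change was -0.53 (camera adjusted p = 5.14e-14; adjusted p = 0.124 with an estimated correlation), or -0.32 under total-signal scaling. RPL22B, at -2.36, and RPS9A, at -1.95, had the smallest p. The gene that rose was RPL15B, at 0.27, and it was named after its value was seen.

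Several other groups were higher at 10 min. Of 40 general stress response genes, 37 rose and 1 fell, with the same counts adjusted over the list alone and a median of 1.49 (camera adjusted p = 8.92e-16; adjusted p = 0.23 with an estimated correlation). Among them were TSL1 of trehalose synthesis (3.57) and the glucokinase gene GLK1 (2.85). Of 11 retrograde response genes, 9 rose and 0 fell, with the same counts adjusted over the list alone and a median of 0.88 (camera adjusted p = 2.06e-05; adjusted p = 0.254 with an estimated correlation). The citrate synthase gene CIT2 (3.51) and the pyruvate carboxylase gene PYC1 (3.38) led them. Of 21 autophagy genes, 16 rose and 0 fell, with the same counts adjusted over the list alone and a median of 0.87 (camera adjusted p = 8.4e-06; adjusted p = 0.124 with an estimated correlation). ATG8 was at 1.56 and ATG19 at 1.17. Of 36 respiratory chain and ATP synthase genes, 30 rose and 1 fell, or 31 and 1 adjusted over the list alone, with a median of 0.49 (camera adjusted p = 9.66e-09; adjusted p = 0.124 with an estimated correlation). CYT1 of complex III was at 1.79 and the succinate dehydrogenase gene SDH2 at 1.56. Of 33 proteasome genes, 14 rose and 0 fell, or 11 and 0 adjusted over the list alone, with a median of only 0.18 (camera adjusted p = 0.00135; adjusted p = 0.344 with an estimated correlation), or 0.39 under total-signal scaling. PRE8 was at 0.35 and RPN7 at 0.29.

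Amino acid biosynthesis genes were lower at 10 min. Of 46 amino acid biosynthesis genes under Gcn4 control, 33 fell and 4 rose, with the same counts adjusted over the list alone and a median of -0.44 (camera adjusted p = 1.95e-05; adjusted p = 0.262 with an estimated correlation), or -0.22 under total-signal scaling. ILV5 was at -1.57 and LEU9 at -1.29, both of branched-chain synthesis. Of 87 spliceosome and splicing factor genes, 44 fell and 5 rose, with the same counts adjusted over the list alone and a median of -0.23 (camera adjusted p = 0.000322; adjusted p = 0.254 with an estimated correlation). Under total-signal scaling the splicing median was -0.02. The distance of both medians from 0 thus depends on the scaling. The helicase gene PRP43, which also serves ribosome assembly, was at -1.77 and CWC2 at -0.97.

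In all, 1645 of 6127 genes were higher and 1848 lower at 10 min in limma's moderated test, and 3758 had an unadjusted p under 0.05. A change of at least 2-fold was shown by 330 higher and 516 lower genes. The libraries of the 2 groups did not overlap for 76.8% of genes, against 33.3% by chance. Scaling each library to its total signal, chosen after seeing the data, gave 2560 higher and 1149 lower genes, since it shifted the median of all genes by 0.21 on the log2 scale. No list kept its call with an estimated correlation. That form of camera uses only the few residual degrees of freedom of the 6 libraries, which leaves little room to pass. The nitrogen list lost its call although its estimated correlation, -0.0038, lay below the preset 0.01. A lost call is thus not by itself evidence of correlation between genes. Across the lists the estimate ran from -0.0143 for the GAL regulon to 0.432 for adenine biosynthesis, with 0.410 for ribosome biogenesis. For lists far above 0.01, the preset correlation may make the camera p too small.

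**Figure D1:**
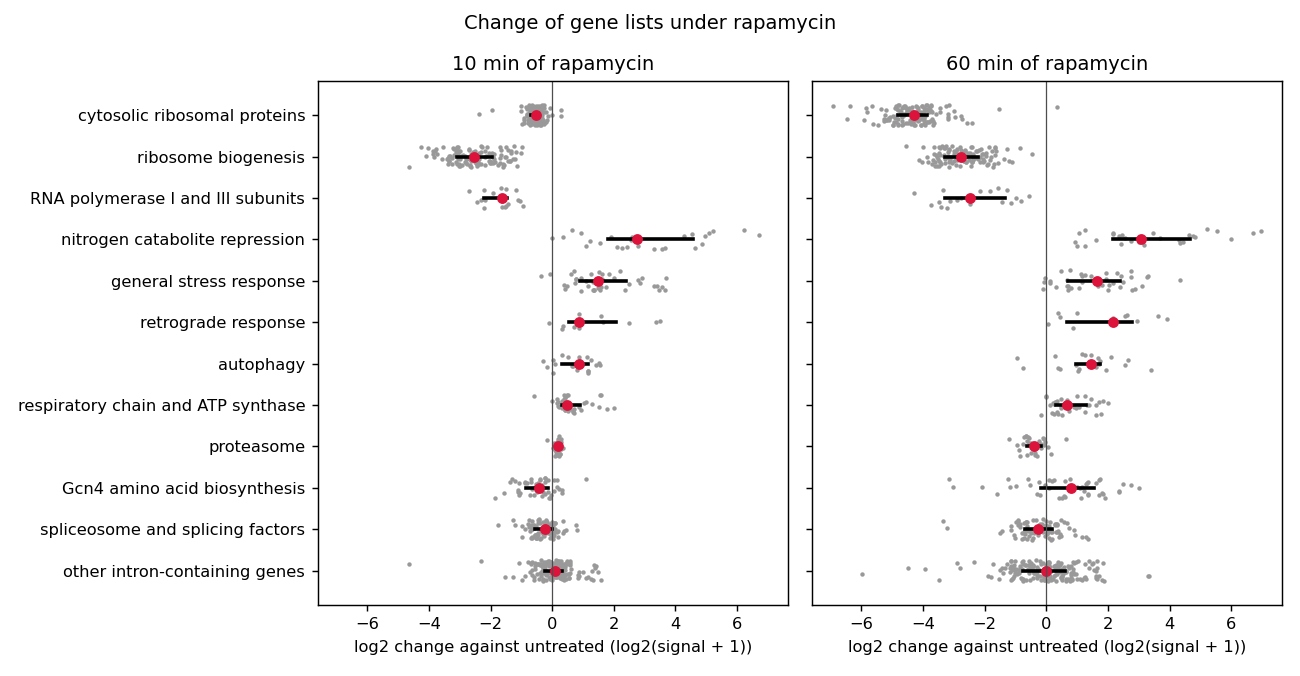
Log2 change against untreated cells, on the log2(signal + 1) scale, for each gene (grey points) of 12 gene groups after 10 min (left) and 60 min (right) of rapamycin. Red points are medians and black lines run between quartiles. The ribosomal protein median lies at -0.53 at 10 min and at -4.31 at 60 min, while the ribosome biogenesis median lies at -2.52 and -2.76.

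The 60 min libraries asked what a longer exposure changed. Ribosomal protein transcripts were by then among the most strongly reduced, with 136 of 137 genes lower and 1, RPL15B at 0.33, higher, and the same counts adjusted over the list alone. The median log2 change was -4.31 (camera adjusted p = 1.27e-34; adjusted p = 0.0757 with an estimated correlation). RPL9A (chromosome VII, 227754 to 228329) fell from 11595 ± 1270 to 95.2 ± 3.40 (scaled signal, mean ± SD, n = 2), a log2 change of -6.91 (SE 0.108, limma adjusted p = 5.23e-09). RPS26B (-6.47), RPS22A (-6.38), RPS16B (-5.92), RPS9B (-5.87), RPS3 (-5.82), RPL26B (-5.64) and RPL12A (-5.61) were also among the 10 largest falls, and RPL5 (-5.48) and RPS18B (-4.98) had the smallest p in the list. Many ribosomal protein genes exist as near-identical pairs, and how shared reads were divided between copies is not given in the sources used here, so the split within a pair is uncertain. The other members of the 10 largest falls were the helicase gene DBP2 (-5.98) and RKI1, which encodes ribose-5-phosphate ketol-isomerase (-5.95).

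Ribosome biogenesis genes stayed low at 60 min. All 121 were lower than in untreated cells, 121 adjusted over the list alone, with a median of -2.76 (camera adjusted p = 9.66e-29; adjusted p = 0.243 with an estimated correlation). GAR1 was at -3.89 and MRT4 at -3.69. All 19 polymerase subunit genes were lower, 19 adjusted over the list alone, with a median of -2.48 (camera adjusted p = 1.03e-07; adjusted p = 0.16 with an estimated correlation). RPA43 was at -4.31 and RPA135 at -3.35.

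Nitrogen genes stayed high. All 28 nitrogen catabolite repression genes were higher at 60 min, 28 adjusted over the list alone, with a median of 3.08 (camera adjusted p = 5.08e-13; adjusted p = 0.0568 with an estimated correlation). DAL80 (chromosome XI, 506898 to 507707) rose from 1.60 ± 0.0890 to 323 ± 15.1 (scaled signal, mean ± SD, n = 2), a log2 change of 6.96 (SE 0.0924, limma adjusted p = 5.02e-09). At so low a starting signal the pseudocount of 1 makes this an understatement. GAP1 (6.71), MEP2 (5.99) and the allantoate permease gene DAL5 (5.55) were also among the 10 largest rises. Joining them were the cell wall gene PIR3 (6.45), GPG1 (5.99), the seripauperin gene PAU2 (5.67) and 3 open reading frames, YCL048W-A (6.48), YLR053C (5.86) and YMR118C (5.68).

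Of 40 stress response genes, 34 were higher and 0 lower at 60 min, or 35 and 0 adjusted over the list alone, with a median of 1.63 (camera adjusted p = 9.79e-09; adjusted p = 0.279 with an estimated correlation). ALD3 was at 2.88 and the trehalase gene NTH1 at 2.76. Of 11 retrograde response genes, 10 were higher and 0 lower, with the same counts adjusted over the list alone and a median of 2.16 (camera adjusted p = 0.000173; adjusted p = 0.262 with an estimated correlation), led by CIT2 (3.91) and PYC1 (3.63). Of 21 autophagy genes, 19 were higher and 2 lower, with the same counts adjusted over the list alone and a median of 1.44 (camera adjusted p = 2.27e-05; adjusted p = 0.124 with an estimated correlation). ATG8 reached 3.39 and ATG34 reached 2.63. Of 36 respiratory genes, 30 were higher and 0 lower, or 31 and 0 adjusted over the list alone, with a median of 0.67 (camera adjusted p = 4.63e-06; adjusted p = 0.164 with an estimated correlation), or 1.35 under total-signal scaling. CYT1 was at 1.98 and QCR9 at 1.84.

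Proteasome genes lay on the other side of 0 at 60 min. Of 33, 26 were lower and 1 higher, with the same counts adjusted over the list alone and a median of -0.39 (camera adjusted p = 0.000835; adjusted p = 0.339 with an estimated correlation), and under total-signal scaling this median turned to 0.29 and the call ended (camera adjusted p = 0.806). PRE2 was at -1.20 and RPN10 at -0.95. Of 46 amino acid biosynthesis genes, 31 were higher and 12 lower, with the same counts adjusted over the list alone and a median of 0.81 (camera adjusted p = 0.00152; adjusted p = 0.344 with an estimated correlation), or 1.49 under total-signal scaling. The arginine gene ARG4 was 8.02-fold higher and the leucine gene LEU1 stood at a log2 change of -3.15. Of 87 splicing genes, 47 were lower and 19 higher, with the same counts adjusted over the list alone and a median of -0.28, or 0.39 under total-signal scaling. That list did not pass (camera adjusted p = 0.0683; adjusted p = 0.413 with an estimated correlation). Its 2 smallest p belonged to PRP43 (-3.37) and SNU13 (-3.22), a protein that also binds small nucleolar RNAs.

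In all, 2365 genes were higher and 2360 lower at 60 min in limma's moderated test, with 4810 at an unadjusted p under 0.05. A change of at least 2-fold was shown by 1020 higher and 1055 lower genes. The libraries did not overlap for 88.1% of genes, against 33.3% by chance. Total-signal scaling, chosen after seeing the data, gave 4002 higher and 1121 lower genes, with a shift of 0.66 in the median of all genes. Without spike-ins, neither split can be preferred from these values.

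Comparing 60 with 10 min directly, the ribosomal protein genes parted furthest. Of 137, 136 were lower at 60 min and 0 higher, with the same counts adjusted over the list alone and a median log2 change of -3.83 (camera adjusted p = 1.48e-45; adjusted p = 0.0505 with an estimated correlation). RPL9A (-6.46), RPS22A (-5.65), RPS26B (-5.55), RPS3 (-5.43) and RPS16B (-5.21) were the 5 largest falls. The 5 largest rises were PIR3 (6.53), YMR118C (5.67), the vitamin B6 genes SNZ1 (5.60) and SNO1 (5.17), and PAU2 (5.30). SNZ1 went from 86.0 ± 5.90 at 10 min to 4229 ± 344 at 60 min (scaled signal, mean ± SD, n = 2). Ribosome biogenesis genes did not shift as a list, with 41 higher and 46 lower, the same counts adjusted over the list alone, and a median of -0.03 (camera adjusted p = 0.392; adjusted p = 0.874 with an estimated correlation). There were 2168 higher and 2069 lower genes in limma's moderated test, with 658 and 549 at 2-fold or more. Total-signal scaling gave 3780 higher and 908 lower, with a shift of 0.45 in the median of all genes.

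IFH1, an activator of ribosomal protein genes (chromosome XII, 582006 to 585490), was measured in the same libraries. Its scaled signal was 162 ± 26.1 in untreated cells, 41.9 ± 0.933 at 10 min and 132.0 ± 0.153 at 60 min (mean ± SD, n = 2). The fall at 10 min was a log2 change of -1.92 (SE 0.107, limma adjusted p = 3.48e-06), and the value at 60 min was higher than at 10 min by 1.63 (SE 0.107, limma adjusted p = 6.95e-06). At 60 min the log2 change against untreated was -0.29 (limma adjusted p = 0.0398). That last call ended when the untreated library numbered 21 was left out, at -0.12 (limma adjusted p = 0.176), or any 10 or 60 min library, and total-signal scaling turned it to 0.39.

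**Figure D2:**
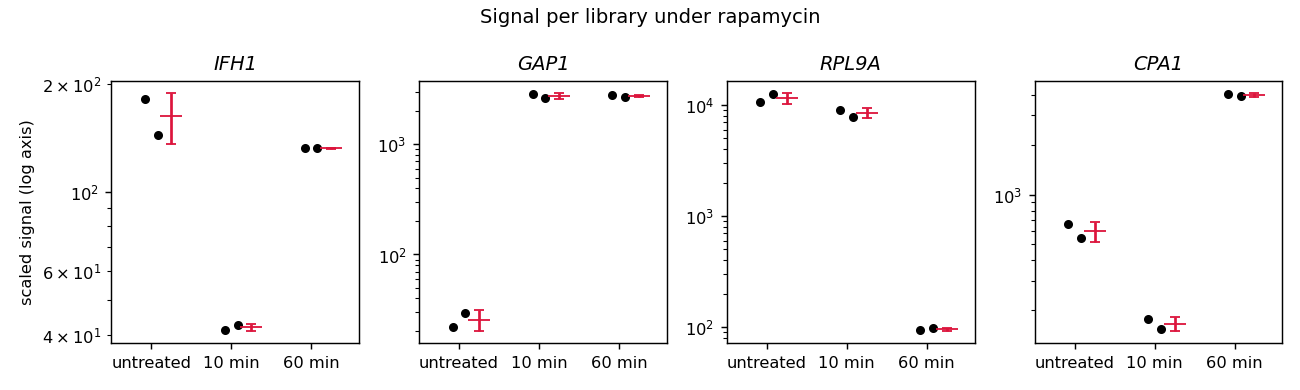
Scaled signal (log axis) of IFH1, GAP1, RPL9A and CPA1 in each library (black points) of untreated cells and after 10 and 60 min of rapamycin, with mean ± SD in red (n = 2 per group). IFH1 is at 41.9 at 10 min and at 132.0 at 60 min, while RPL9A drops to 95.2 only at 60 min.

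The calls at the 2 times overlapped. There were 1291 genes higher at both and 1416 lower at both, 2707 in all, against 1347 for independent lists of the same sizes. Simulated unchanged groups, with simulated untreated libraries shared by both times, gave 0.02 on average, and at most 1, over 50 simulations. Almost no gene is called where nothing changes, so that value cannot tell how much the shared libraries add to the overlap. Log2 changes correlated across genes at r = 0.666, and simulation without effects gave 0.500. The covariance was 0.804 against 0.00991 simulated, a difference of 0.795. Setting each time against a different untreated library, chosen after seeing the data, gave 2687 and 2659 shared calls for the 2 ways of doing so, against 1439 and 1330 for independent lists, and covariances of 0.780 and 0.789.

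The title of the series concerns competition between pre-mRNAs for splicing, so intron-containing genes were set apart. By the deposited gene models, and R64 for genes these lack, there were 280 of them, 97 ribosomal protein genes and 183 other genes. Ribosomal protein genes with introns had a median log2 change of -0.54 at 10 min (82 of 97 lower, 0 higher, 87 lower adjusted over the list alone; camera adjusted p = 1.7e-13; adjusted p = 0.0889 with an estimated correlation) and -4.37 at 60 min. All 97 were lower at 60 min, 97 adjusted over the list alone (camera adjusted p = 2.51e-30; adjusted p = 0.0568 with an estimated correlation). The 40 without introns had medians of -0.48 and -4.22, with 34 lower and 1 higher at 10 min and 39 lower and 1 higher at 60 min, and the same counts adjusted over the list alone. Their camera adjusted p was 2.06e-05 at 10 min (adjusted p = 0.254 with an estimated correlation) and 5.12e-15 at 60 min (adjusted p = 0.124 with an estimated correlation). Under total-signal scaling the 10 min medians were -0.33 with introns and -0.27 without. Of the 182 other intron-containing genes that were tested, some rose and some fell. At 10 min 54 rose and 43 fell, or 53 and 43 adjusted over the list alone, with a median of 0.09 (camera adjusted p = 0.224), or 0.30 under total-signal scaling (camera adjusted p = 0.172). At 60 min 68 rose and 77 fell, the same adjusted over the list alone, with a median of -0.03 (camera adjusted p = 0.715), or 0.63 under total-signal scaling (camera adjusted p = 0.914).

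Shares of the summed signal do not depend on the scaling of a library. Intron-containing genes made up 17.4 ± 0.617% of it in untreated cells, 14.4 ± 0.103% at 10 min and 3.84 ± 0.00288% at 60 min (mean ± SD, n = 2). Ribosomal protein genes held 86.4 ± 0.106%, 82.4 ± 0.0673% and 30.6 ± 0.287% of that intron-containing signal. Other intron-containing genes held 2.36 ± 0.0654%, 2.54 ± 0.00845% and 2.67 ± 0.00904% of the whole. With 2 libraries against 2, an exact permutation test cannot go below a two-sided p of 0.333, so none is given. Weighting signal by exon length, chosen after seeing the data, gave 10.1%, 8.31% and 2.52% for all intron-containing genes and 79.6%, 74.6% and 21.0% for the ribosomal protein part. For other intron-containing genes it gave 2.06%, 2.11% and 1.99%, so the direction of their share from untreated to 60 min depends on the weighting. Spliced and unspliced forms are not told apart by these values.

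**Figure D3:**
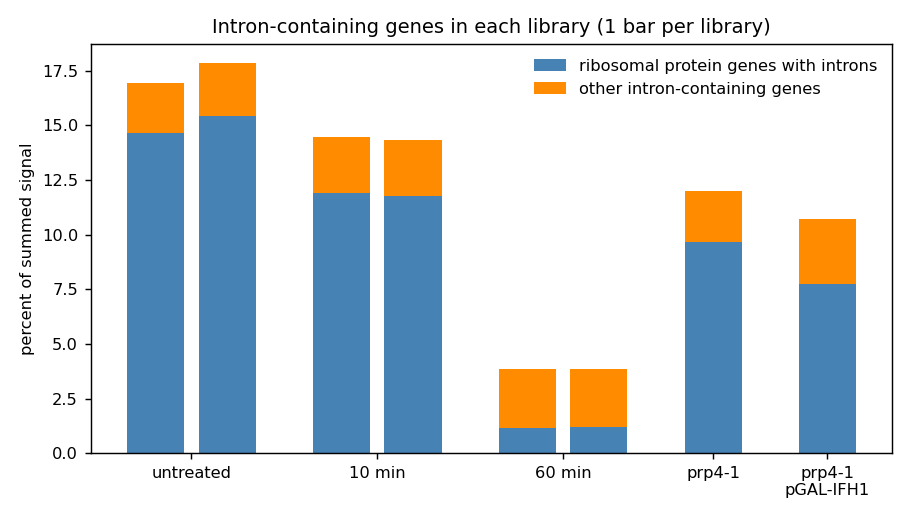
Percent of summed signal from ribosomal protein genes with introns (blue) and from other intron-containing genes (orange), with 1 bar per library. The blue part averages 15.0% in untreated cells, 11.9% at 10 min and 1.18% at 60 min, while the orange part stays between 2.34% and 2.98% in the group means.

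The prp4-1 pair asked what lower IFH1 did in a strain with a splicing mutation. With 1 library each there is no replicate check and no test, so ratios describe these libraries only. IFH1 had a scaled signal of 154 in prp4-1 and 86.1 in prp4-1 pGAL-IFH1, which is 55.9% and a log2 ratio of -0.83. PRP4 was at 121 and 105. Both libraries had the MATα markers, with MF(ALPHA)1 at 13001 and 21822, against the a-specific gene STE2 at 22.5 and 28.7. GAL1 was low in both, at 12.9 and 13.7. Some markers differed between the 2 libraries. MET17 was at 1495 in prp4-1 and listed at 0 in prp4-1 pGAL-IFH1, URA3 was at 111 and listed at 0, and LEU2 was at 1386 and 622. AIF1 was listed at 0 in prp4-1 and was at 195 in the other strain.

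Ribosomal protein genes were lower in prp4-1 pGAL-IFH1, in 115 of 137, with a median log2 ratio of -0.47 and quartiles of -0.72 and -0.16. None of 10000 random lists matched on mean signal had a lower median (percentile 0), and their own median was -0.19. The pools they were drawn from include the ribosomal protein genes themselves. Those with introns had a median of -0.48 (percentile 0.04) and those without -0.41 (percentile 8.36). The other intron-containing genes had a median of 0.08 (percentile 73.7). Ribosomal protein genes with introns made up 9.66% of summed signal in prp4-1 and 7.74% in prp4-1 pGAL-IFH1, against 2.34% and 2.98% for other intron-containing genes. They held 80.5% and 72.2% of the intron-containing signal.

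Ribosome biogenesis genes lay in the opposite direction, higher in all 121 with a median of 1.29 (percentile 100), as did the 19 polymerase subunit genes, with a median of 1.06 (percentile 100). Splicing genes had a median of 0.26 (percentile 100), higher in 68 of 87. General stress response genes were lower in all 40, with a median of -2.48 (percentile 0). Their share of summed signal was 0.892% in prp4-1 and 0.140% in prp4-1 pGAL-IFH1. It averaged 0.222% in untreated wild type, so for this list the prp4-1 library was the one with a high share. For ribosome biogenesis genes the share was 1.58% in prp4-1, 4.11% in prp4-1 pGAL-IFH1 and 1.90% in untreated wild type. There prp4-1 pGAL-IFH1 stood apart. Wild type also differed from the pair in strain and growth temperature. Respiratory genes were lower in all 36, with a median of -1.36 (percentile 0), and proteasome genes in all 33, with a median of -0.51 (percentile 0.1). Medians of -1.14 (percentile 0.02) for the retrograde response, -0.88 (percentile 0.01) for autophagy and -0.76 (percentile 0.01) for nitrogen catabolite repression were also low. Amino acid biosynthesis genes stood at -0.03 (percentile 16.7), or 0.08 under total-signal scaling.

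Among single genes with a mean signal of at least 10, the 4 asparaginase copies had the largest ratios, ASP3-3 (log2 ratio 7.20), ASP3-4 (6.98), ASP3-1 (6.74) and ASP3-2 (6.49). They lie on chromosome XII between 469317 and 487289 and are near-identical, so their separate values are uncertain. Their signal was 1.37 to 2.90 in prp4-1 and 347 to 359 in prp4-1 pGAL-IFH1. In untreated wild type, not set on a common scale, it was 330 to 373. The prp4-1 library was thus the low one. Next in ratio came YLR342W-A (4.91), the drug transporter gene QDR2 (3.50), the small nucleolar RNA genes snR65 (3.02) and snR56 (2.92), YOR041C (2.92) and the subtelomeric gene COS12 (2.79). Since poly(A) RNA was sequenced, values of small RNA genes need not follow the level of forms without a poly(A) tail. The lowest ratios were those of YER053C-A (-8.44), the flocculin gene MUC1 (-6.80), YRO2 (-6.53), YGP1 (-6.40), YKL071W (-5.59), HMS1 (-5.57), the hexokinase gene HXK1 (-5.46), the polyamine transporter gene TPO2 (-5.17), the plasma membrane heat shock gene HSP30 (-5.11) and the phosphate transporter gene PHO84 (-5.10). Of 6222 genes with a mean signal of at least 1, 529 were at least 2-fold higher and 714 at least 2-fold lower.

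**Figure D4:**
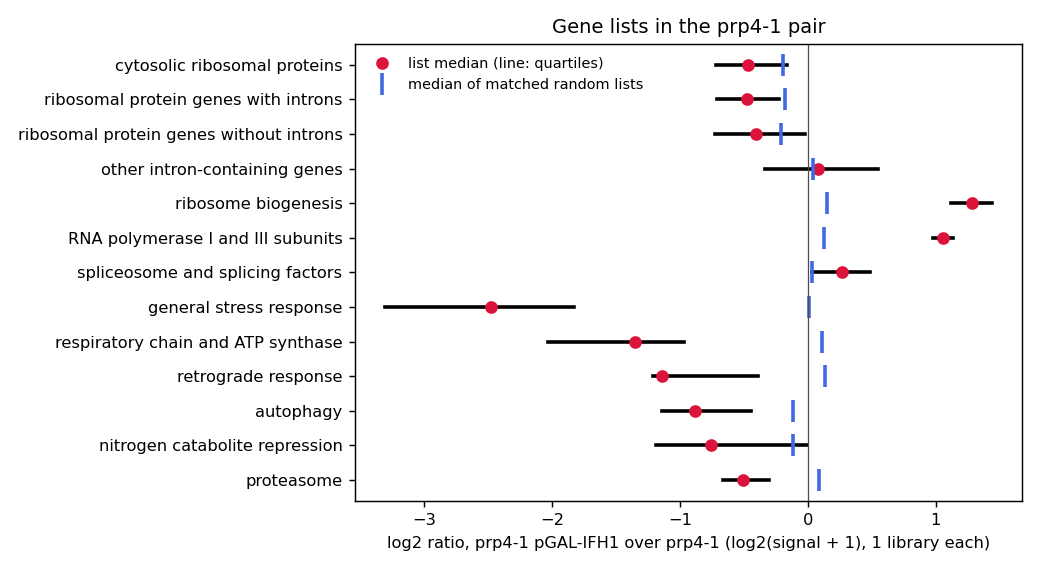
Log2 ratio of prp4-1 pGAL-IFH1 over prp4-1, on the log2(signal + 1) scale with 1 library each, for 13 gene groups. Red points are list medians, black lines run between quartiles and blue marks are the medians of random lists matched on mean signal. The ribosomal protein median is -0.47, the ribosome biogenesis median 1.29 and the stress response median -2.48.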

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

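All tests below on the prp4-1 pair, and the test of scaling on genes with opposite calls, were chosen after the results were seen, while the test of single libraries was not.

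The effects at 10 and 60 min of rapamycin differed in a direct test for 4237 genes and 12 lists. The median log2 difference, 60 minus 10 min, was -3.83 for ribosomal protein genes (136 of 137 lower, 136 adjusted over the list alone; camera adjusted p = 1.48e-45; adjusted p = 0.0505 with an estimated correlation). It was -3.83 for those with introns (97 of 97 lower, 97 adjusted over the list alone; camera adjusted p = 2.07e-39; adjusted p = 0.0432 with an estimated correlation), which was the only list that passed that way. For those without introns it was -3.80 (39 of 40 lower, 39 adjusted over the list alone; camera adjusted p = 9.05e-20; adjusted p = 0.11 with an estimated correlation).

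These 6 lists were also lower at 60 than at 10 min. Total-signal scaling raises the median of all genes by 0.45 in this comparison. It would make these falls smaller and the rises given next larger. G1 cyclins and histones stood at -1.10 (15 of 16 lower, 15 adjusted over the list alone; camera adjusted p = 2.31e-05; adjusted p = 0.0995 with an estimated correlation). Polymerase I and III subunits stood at -0.89 (13 of 19 lower and 5 higher, the same adjusted over the list alone; camera adjusted p = 0.0143; adjusted p = 0.362 with an estimated correlation). Proteasome genes stood at -0.63 (30 of 33 lower and 1 higher, the same adjusted over the list alone; camera adjusted p = 2.85e-07; adjusted p = 0.23 with an estimated correlation). Hsf1 chaperones stood at -0.61 (15 of 19 lower and 2 higher, the same adjusted over the list alone; camera adjusted p = 0.00138; adjusted p = 0.23 with an estimated correlation). Mitochondrial ribosomal proteins stood at -0.33 (47 of 73 lower and 8 higher, 48 and 8 adjusted over the list alone; camera adjusted p = 0.000176; adjusted p = 0.0995 with an estimated correlation), less than the shift of 0.45 that total-signal scaling brings. Autoregulated genes with introns, of which 3 are ribosomal protein genes, stood at -2.48 (5 of 7 lower and 1 higher, the same adjusted over the list alone; camera adjusted p = 0.00781; adjusted p = 0.23 with an estimated correlation).

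These 3 lists were higher at 60 than at 10 min. Amino acid biosynthesis genes stood at 1.01 (36 of 46 higher and 6 lower, 36 and 8 adjusted over the list alone; camera adjusted p = 2.08e-07; adjusted p = 0.23 with an estimated correlation). Adenine biosynthesis genes stood at 0.73 (9 of 11 higher and 2 lower, the same adjusted over the list alone; camera adjusted p = 0.0133; adjusted p = 0.481 with an estimated correlation). Autophagy genes stood at 0.48 (16 of 21 higher and 2 lower, the same adjusted over the list alone; camera adjusted p = 0.00361; adjusted p = 0.226 with an estimated correlation).

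Opposite calls at the 2 times were made for 316 genes, 119 higher then lower and 197 lower then higher. The arginine gene CPA1 went from 602 ± 82.3 to 166 ± 15.7 and then 3995 ± 110 (scaled signal, mean ± SD, n = 2). Changes of at least 2-fold in both directions were shown by 12 genes. YOR302W, CPA1, YOR338W, TEA1, ICY2, RAD28, ARG3, MCH5 and HIS4 went down and then up, while OPT1, ISF1 and SPS4 went up and then down. YOR302W (chromosome XV, 882765 to 882842) lies directly before CPA1 (882899 to 884134) on the same strand. Its log2 changes of -1.98 and 2.73 were close to those of CPA1, -1.85 and 2.73, so these 2 may not be separate cases. The same holds for TEA1 (954344 to 956623) and YOR338W (956898 to 957989), neighbours on 1 strand of chromosome XV. Their log2 changes were -1.72 and 1.87 for TEA1, and -1.75 and 1.43 for YOR338W. All 12 had opposite calls under total-signal scaling and with each library left out. For total-signal scaling that result was all but set by how the 12 were chosen. It shifts the median of all genes by 0.21 at 10 min and 0.66 at 60 min on the log2 scale. Both shifts are smaller than a 2-fold change, so this is no test of scaling. Total-signal scaling gave 276 genes with opposite calls, 53 higher then lower and 223 lower then higher. Of the 316, only 90 were among them, and without a spike-in neither scaling can be preferred, so for the other genes scaling and a true reversal cannot be told apart. Leaving out a library gave 173 to 350 such genes, and 116 were called in every case. All 316 had both libraries of each time beyond both untreated libraries, but so had every called gene, so that test could not have shown a single library at work.

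In the prp4-1 pair, ribosomal protein transcripts were lower while ribosome biogenesis transcripts were higher and stress transcripts lower. A growth or stress state that moves both ribosome lists the same way was considered for the ribosomal protein list. That list's median log2 ratio was -0.47, against 1.29 for ribosome biogenesis. These opposite directions define the pattern and rest on 1 library per strain, so they cannot test that state. For the stress and ribosome biogenesis lists a growth or stress state may account for the change. Outside the 4 lists of the pattern, log2 ratios in the pair correlated with the 10 min rapamycin change at r = -0.46 across 5771 genes, which are not independent replicates. Lower IFH1, at a log2 ratio of -0.83, stays open for the ribosomal protein list. So do other differences between the strains, since 4 genes (AIF1, HMS1, MET17 and URA3) were under 1 in 1 library and above 20 in the other. That cut leaves out the ASP3 copies, at 1.37 to 2.90 in prp4-1 and 347 to 359 in prp4-1 pGAL-IFH1. With 1 library per strain, lower IFH1 and other strain differences cannot be told apart.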

How the results depend on the processing

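Total-signal scaling in wild type, the set of library numbers as a term, median-of-ratios scaling of the pair, weighting by exon length, split untreated libraries for the overlap and all alternatives for genes with opposite calls were chosen after the results were seen.

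Both median-of-ratios scalings, no filter, a pseudocount of 0.1 and the set of library numbers as a term left every count of called genes within 1.5 times its value. Median-of-ratios scaling over all genes tests little here, since such factors of the scaled signal already lay within 0.417% of 1. Fits of only the 4 libraries compared gave 3130 genes at 10 min, 4591 at 60 min and 4564 between the times. In them the calls of SPO22 (0.55, limma adjusted p = 0.0984) and STE2 (-0.25, limma adjusted p = 0.0587) at 10 min and of IFH1 (-0.29, limma adjusted p = 0.0658) at 60 min ended. Leaving out 1 library gave 2600 to 3751 genes at 10 min, 4214 to 4768 at 60 min, 3519 to 4568 between the times, 2149 to 2876 in the overlap and 31 to 34 list calls. Genes with opposite calls ranged from 173 to 350. Fewer were called without a 10 or 60 min library than without an untreated library, though each such fit leaves a group with 1 library.

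Total-signal scaling gave 2560 higher and 1149 lower genes at 10 min, 4002 and 1121 at 60 min, and 3780 and 908 between the times, because it moves all genes by 0.21, 0.66 and 0.45. By the same shift, values at 60 min turned to 0.39 for ADE2 and 0.39 for IFH1, and list medians to 0.33 for mitochondrial ribosomal proteins, 0.0664 for Hsf1 chaperones, 0.29 for the proteasome and 0.17 for mRNA decay. These 4 list calls ended as well. Camera compares a list with other genes, which shift too, so why the calls ended was not tested. The calls of the decay list at 10 min (-0.06) and the meiotic list at 60 min (1.47) ended too. Weighting by exon length turned the share of other intron-containing genes from a value that was higher at 60 min than in untreated cells to one that was lower, 2.06% against 1.99%. A 2-fold minimum, which can only remove genes, left 846 (330 higher, 516 lower) at 10 min, 2075 (1020 and 1055) at 60 min, 1207 (658 and 549) between the times and 672 in the overlap.

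With an estimated correlation 0 lists were called at 10 or 60 min, against 34 with the preset correlation. The estimated form has few residual degrees of freedom, and the nitrogen list lost its call at an estimated correlation of -0.0038. Lost calls are thus not by themselves evidence of correlation between genes. Estimates ran from -0.0143 to 0.432 over the lists, against the preset 0.01. For lists far above it, such as ribosome biogenesis at 0.410, the camera p with the preset correlation may be too small. The fry test, which asks whether the genes of a list move on balance one way and compares them with no other genes, called 42. The ribosomal protein medians of -0.53 and -4.31 and the ribosome biogenesis medians of -2.52 and -2.76 are unaffected, since only the test differs. The ribosomal protein median in the prp4-1 pair was -0.36 under total-signal scaling, which moves the genes of the pair by 1 factor, 0.11 at the median gene. Of 46 results for the pair, 7 moved by more than the spread used under that scaling, 11 with a pseudocount of 0.5 and 23 with a pseudocount of 5. None of them changed sign with either pseudocount. Under total-signal scaling 2 did, the amino acid biosynthesis median to 0.08 and the meiotic median to 0.02.

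Some calls near the threshold ended when 1 library was left out, among them SPO22 and STE2 at 10 min, STE3, ADE2 and IFH1 at 60 min, the decay list at both times and the meiotic list at 60 min. No paired analysis was possible because the columns carry no replicate number. Nothing in the labels says that library numbers 21 to 23 and 24 to 26 are sets. Taken as sets and added as a term, they gave 3303, 4632 and 4123 genes at 10 min, at 60 min and between the times, and the SPO22 call at 10 min ended. Deviations from group means correlated between the groups at -0.115, -0.0834 and 0.156 across genes.

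The overlap was 2687 and 2659 genes with each time set against a different untreated library. Planned splicing results with their alternatives, edgeR and DESeq2 and a block for replicate number were not run, since the files analysed hold no intron values, counts or replicate numbers. Depth is unknown, so its limit cannot be given.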

Other observations

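The families of small RNA and PAU genes were chosen after the results were seen.

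G1 cyclins and histones did not pass as a list at 10 min, at a median log2 change of -0.14 with 4 of 16 lower and 1 higher (3 and 0 adjusted over the list alone; camera adjusted p = 0.348). At 60 min the median was -1.40, with 14 lower and 0 higher (15 and 0 adjusted over the list alone; camera adjusted p = 9.44e-05; adjusted p = 0.124 with an estimated correlation), or -0.72 under total-signal scaling. CLB6 was at -2.49 and FAR1 at -1.61 at 60 min, and FAR1 at -0.84 and CLN3 at -0.67 at 10 min.

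Adenine biosynthesis genes were lower at 10 min, at a median of -0.98 with 10 of 11 lower and 0 higher (the same adjusted over the list alone; camera adjusted p = 6.53e-05; adjusted p = 0.262 with an estimated correlation). MTD1 was at -1.16 and ADE17 at -1.18. At 60 min the list stood at -0.06 with 4 higher and 5 lower, the same adjusted over the list alone (camera adjusted p = 0.765), and ADE5,7 at -1.43 and ADE13 at -0.98 had the smallest p.

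Messenger RNA decay genes had a median of -0.28 at 10 min, with 6 of 11 lower and 0 higher (7 and 0 adjusted over the list alone; camera adjusted p = 0.0268; adjusted p = 0.392 with an estimated correlation). UPF3 was at -0.88 and NAM7 at -0.65. The call ended without the untreated library numbered 21 (-0.30, camera adjusted p = 0.0686) or the 10 min library numbered 22 (-0.23, camera adjusted p = 0.0507), and under total-signal scaling (-0.06, camera adjusted p = 0.0929). At 60 min the median was -0.50, or 0.17 with no call under total-signal scaling (camera adjusted p = 0.467), with 9 lower and 1 higher, the same adjusted over the list alone (camera adjusted p = 0.0322; adjusted p = 0.399 with an estimated correlation). DCP1 was at -1.09 and EDC3 at -1.01, and the call ended without the untreated library numbered 21 (-0.43, camera adjusted p = 0.0598).

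Mitochondrial ribosomal protein genes had 8 of 73 higher and 7 lower at 10 min (5 and 4 adjusted over the list alone), a median of -0.03 and a mean of 0.00431, which differ in sign (camera adjusted p = 0.765). RSM10 was at 0.74 and YMR31 at 0.80. At 60 min the median was -0.35, or 0.33 with no call under total-signal scaling (camera adjusted p = 0.869), with 46 lower and 11 higher, the same adjusted over the list alone (camera adjusted p = 0.00715; adjusted p = 0.124 with an estimated correlation). MRPL20 was at -1.14 and MRPL31 at -0.91. Hsf1 chaperones stood at 0.09 at 10 min, or 0.30 under total-signal scaling. At 10 min 7 of 19 were higher and 4 lower, the same adjusted over the list alone (camera adjusted p = 0.336). YDJ1 was at -0.67 and HSP82 at 0.69. At 60 min their median was -0.61, or 0.0664 with no call under total-signal scaling (camera adjusted p = 0.199), with 14 lower and 3 higher, the same adjusted over the list alone (camera adjusted p = 0.0234; adjusted p = 0.288 with an estimated correlation), and SSA2 was at -1.77.

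Autoregulated genes with introns had medians of -0.70 at 10 min, with 5 of 7 lower and 0 higher, the same adjusted over the list alone (camera adjusted p = 0.0243; adjusted p = 0.254 with an estimated correlation), and -3.25 at 60 min. There 6 were lower and 0 higher, the same adjusted over the list alone (camera adjusted p = 0.00155; adjusted p = 0.178 with an estimated correlation). DBP2 was at -2.31 and then -5.98, and RPS14B at -3.82 at 60 min.

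Meiotic genes had a median of 0.32 at 10 min, with 1 of 15, SPO22, higher (0 adjusted over the list alone; camera adjusted p = 0.149). At 60 min it was 0.97, with 11 higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.0473; adjusted p = 0.254 with an estimated correlation), a call that ended without untreated library 21 (1.01, camera adjusted p = 0.0512), untreated library 24 (0.89, camera adjusted p = 0.0538) or 60 min library 26 (0.82, camera adjusted p = 0.1). It also ended under total-signal scaling (1.47, camera adjusted p = 0.427) and with a pseudocount of 0.1. The SPO22 call at 10 min ended without each library except the untreated library numbered 24, at 0.49 to 0.55 (limma adjusted p = 0.0754 to 0.118). SPO1 was at 1.86 and SPO22 at 1.64, and the gene models used here show no intron in SPO13 and MEK1. The GAL regulon stood at 0.36 at 10 min, with 2 of 8 higher and 0 lower (camera adjusted p = 0.148), and at 0.23 at 60 min, with 4 higher and 1 lower (camera adjusted p = 0.277), the same counts adjusted over the list alone at both times. GCY1 was at 1.04 and 2.37 and GAL7 at 1.06 and 2.22. Under total-signal scaling the GAL regulon medians were 0.54 and 0.88, and the meiotic median at 10 min was 0.49.

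Among label checks, the a-specific list had 1 of 7 higher and 1 lower at 10 min (1 and 0 adjusted over the list alone), a median of -0.14 (camera adjusted p = 0.994), and -0.44 at 60 min, with 2 higher and 4 lower, the same adjusted over the list alone (camera adjusted p = 0.424). The alpha-specific list stood at 0.26 with 0 of 4 called at 10 min (camera adjusted p = 0.454) and 0.60 with 2 higher at 60 min (camera adjusted p = 0.336), the same adjusted over the list alone. MF(ALPHA)1 had a scaled signal of 12.7 in 1 of the 10 min and 15.5 in 1 of the 60 min libraries, and 1.92 to 5.02 in the other wild-type libraries. In each group the library numbered 24, 25 or 26 was higher than the one numbered 21, 22 or 23. The same held for MF(ALPHA)2 and LEU2, which were also low. URA3 was listed at 0 in all 6. The 1 auxotrophic marker tested, ADE2, was at -0.55 at 10 min and at -0.29 at 60 min, or 0.39 under total-signal scaling. The call at 60 min ended without the 60 min library numbered 26 (-0.25, limma adjusted p = 0.0696). Under total-signal scaling the medians of lists that did not pass changed sign for the a-specific genes (0.08 at 10 min, 0.24 at 60 min), G1 cyclins and histones at 10 min (0.07), mitochondrial ribosomal proteins at 10 min (0.19) and adenine biosynthesis at 60 min (0.61). So did those of splicing genes (0.39) and other intron-containing genes (0.63) at 60 min. The alpha-specific medians became 0.44 at 10 min and 1.24 at 60 min.

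In the prp4-1 pair, log2 ratios had medians of -0.59 for Hsf1 chaperones (percentile 0.46), 0.42 for decay genes (94.1), 0.22 for G1 cyclins and histones (93.3), 0.17 for adenine biosynthesis (49.5), 0.10 for mitochondrial ribosomal proteins (38.4), -0.08 for meiotic genes (61.8), 0.12 for the GAL regulon (75.8), 0.43 for autoregulated genes (87.8), -0.63 for a-specific genes (17.4), 0.47 for alpha-specific genes (94.3) and -3.98 for 4 auxotrophic markers (percentile 0).

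Small nucleolar and nuclear RNA genes had a median of -0.37 at 10 min, with 21 of 69 lower and 1 higher, -1.05 at 60 min, with 37 lower and 11 higher, and 1.17 in the prp4-1 pair. The libraries were of poly(A) RNA, so these values need not follow the level of forms without a poly(A) tail. PAU genes, near-identical in sequence, had 0.35, with 4 of 23 higher and 1 lower, then 2.83, with 21 higher and 0 lower, and -1.62 in the pair. With the shift of total-signal scaling added, the medians of the small RNA genes were -0.17, -0.38 and 1.29, and those of the PAU genes 0.55, 3.49 and -1.50.

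For 8 genes lying within a gene of the opposite strand that had a signal of at least 1000, the inner gene had at most 0.273% of the outer gene's signal, with a median of 0.00493%.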
